A study of Mus musculus with 6 samples.

How the data were processed

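Whole small intestinal tissue of C57BL/6 mice aged 12 weeks was measured by poly(A) RNA sequencing with a directional library kit and single-end reads. The 6 libraries fall into 2 groups of 3 mice. The WT intestine samples came from mice without the Villin-Cre transgene that carried floxed alleles of both atypical protein kinase C genes, Prkci (PKC lambda/iota) and Prkcz (PKC zeta). The DKO tumour samples were tumours of mice in which Villin-Cre, a recombinase expressed in intestinal epithelium, deletes both genes. Genotype and tissue type changed together, so neither can be separated from the other. Samples of non-tumour DKO intestine were not analysed here.

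The deposited table holds raw read counts per gene symbol, with 1 column per mouse. The title of the deposited sheet names normal DKO tissue, whereas its column headers name the DKO tumour samples, and the headers were followed. The submitters' processing notes name STAR, DESeq2 and the mouse genome build mm10, without versions. The read counter, the gene annotation and the strand setting are not given in the sources used here, so reads shared between near-identical genes were handled in a way that the counts do not show. The values are whole numbers with unequal totals, and they were used as counts. A deposited comparison of WT with non-tumour DKO intestine was planned as a further result, but the table used here holds counts only, so it was not run.

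Of 23420 rows, 27 carried a spreadsheet date in place of a gene name and were set aside. They held between 0.218% and 0.24% of the counts of a library. Of the 23393 named genes, 5082 had no count in any library, and 22968 symbols (98.18%) matched the GENCODE M21 annotation of the same build, from which coordinates were taken. The table uses older symbols for some genes. Totals over named genes were 12785595, 13496246 and 15799269 counts for WT intestine 1 to 3 and 15105393, 13687197 and 12491561 counts for DKO tumours 1 to 3.

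Genes with at least 10 counts in 3 or more libraries were kept, which left 13866. They were compared with the quasi-likelihood test of edgeR 4.0.16 after TMM scaling, in R 4.3.3, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are DKO tumour over WT intestine on the log2 scale, with their standard error (SE). Levels are CPM (library-scaled counts, edgeR cpm) on the TMM scale and are shown as mean and SD over 3 libraries. The square root of the common dispersion was 0.227. On simulated data with the same depths, 36 of 100 genes changed by 2-fold and 92 of 100 changed by 4-fold were recovered, and 6 of 134 calls (4.48%) were false. Far fewer genes changed there than were called in the data, so the threshold on the unadjusted p was stricter. These shares are therefore not the recovery in the data themselves.

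Before the data were examined, 40 gene lists were fixed, with 615 entries, of which 590 were in the table (6 of them through a synonym). The mitochondrially encoded list had no gene in the table. For each list, members past the threshold were counted over all genes tested and adjusted over the list alone, and the 36 lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation as the alternative. The genes named were chosen by a rule fixed at the same time. It takes Prkci and Prkcz, the 10 largest rises and 10 largest falls among called genes with a mean of at least 100 counts (passing over unnamed gene models and receptor segments), up to 4 members with the smallest adjusted p of each list with a call or 3 changed members, and 12 fixed genes. The text prints part of them. Other genes it names, such as Duox2, Axin2, Smad7, Ido1, Tff2, Muc6, Fabp6, Ctrb1 and Car3, were chosen after their values were seen.

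Where WT libraries held no read of a gene, the fold is a lower bound against a floor of 3 counts over the group. Where they held 1 to 3 counts in total, the ratio carries a 95% exact (Clopper-Pearson) interval. Both were computed on counts pooled over the 3 mice of a group, so they cover counting error only and not variation between mice. Reads carried no molecular identifiers.

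The alternatives were the DESeq2 1.42.0 test, DESeq2 size factors, no filter, a filter of 50 counts, a minimum log2 change of 1, a block by replicate number, and leaving out each library. Further choices were added after the data had been seen, namely library totals and upper-quartile factors in place of TMM, and leaving out each tumour while keeping the genes tested with all libraries.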

Results

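The transcriptome of small intestinal tumours that arise when both atypical protein kinase C genes are deleted in the intestinal epithelium (DKO tumour, n = 3 mice) was compared with that of intestine of control mice without the recombinase (WT intestine, n = 3 mice). The study's title places the question in serrated intestinal cancer and immune surveillance. Library totals ranged from 12491561 to 15799269 counts. Spearman correlations between libraries were 0.980 to 0.987 within WT intestine, 0.975 to 0.983 among tumours and 0.959 to 0.965 between the groups. The first principal component held 71.7% of the variance and separated the groups, and the second (12.4%) separated DKO tumour 1 from DKO tumour 2.

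Of the targeted genes, Prkcz (chromosome 4, 155260129 to 155361361) fell in DKO tumours and Prkci (chromosome 3, 30995747 to 31052959) did not. Prkcz was at 66.9 CPM (SD 5.26, n = 3) in WT intestine and 16.8 CPM (SD 2.33, n = 3) in tumours, a log2 fold change of -1.99 (SE 0.152, edgeR adjusted p = 0.000233), and every tumour was below every WT library. Prkci was at 70.6 CPM (SD 15) in WT intestine and 93.9 CPM (SD 12) in tumours, a log2 fold change of 0.41 (SE 0.187, edgeR adjusted p = 0.134). These are counts over the whole gene in whole tissue, so they do not separate a shortened transcript from a full one, nor epithelial from other cells.

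The gastric-type gene Anxa10 rose and the Paneth cell gene Mptx2 fell in DKO tumours. Anxa10, an annexin of gastric epithelium (chromosome 8, 62057042 to 62123150), was at 0.133 CPM (SD 0.0552, n = 3) in WT intestine and 405 CPM (SD 120, n = 3) in tumours, with a log2 fold change of 11.51 (SE 0.429, edgeR adjusted p = 2.01e-05). Mptx2, a mucosal pentraxin of Paneth cells (chromosome 1, 173274382 to 173277777), went from 493 CPM (SD 47.8) to 3.43 CPM (SD 2.97), a log2 fold change of -7.14 (SE 0.584, adjusted p = 0.000283), and of -8.16 without DKO tumour 1. In all, 2211 genes rose and 1911 fell among the 13866 tested, and 1230 of the rises and 985 of the falls had a log2 fold change of at least 1 in size. The groups did not overlap in 6651 genes (48%; chance gives 10%). Without WT intestine 2, DKO tumour 2 or DKO tumour 3 the total of 4122 genes was 2175, 2733 or 1866. The balance of rises and falls depended on scaling, with 3779 rises and 1065 falls under library totals, which shift the median of all genes by 0.258 on the log2 scale.

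Of the 10 largest rises, 9 were in genes with a WT mean below 0.5 CPM, the exception being Akp3. Dpcr1 was at least 556-fold higher in DKO tumours, with a WT total of 0 counts. It was at 32.3, 3.09 and 101 CPM in DKO tumours 1 to 3, and the bound was 240 without DKO tumour 3. Syt8, a synaptotagmin, was 1470 times higher (95% interval 406 to 12100; log2 fold change 10.32, and 9.67 without WT intestine 3) and Cfhr2, a complement factor H relative, 556 times higher (154 to 4590), each with 2 WT counts in total. Cfhr2 was at 54.9, 1.68 and 26 CPM in DKO tumours 1 to 3, and the ratio was 256 without DKO tumour 1. Atg9b rose by 7.51 on the log2 scale (SE 0.344), from 0.463 to 86.2 CPM. Wfdc18 was at least 331-fold higher, with 61.9, 2.95 and 5.78 CPM in DKO tumours 1 to 3 and a bound of 55.4 without DKO tumour 1. Akp3, an intestinal alkaline phosphatase, was at 3388, 4.03 and 544 CPM in these tumours and at 24.2, 1.73 and 2.53 CPM in WT libraries 1 to 3. It differed by 7.14 on the log2 scale (SE 2.12), by 4.89 without DKO tumour 1, by 7.73 without DKO tumour 2 and by 9.25 without WT intestine 1. The order of the tumours for Akp3 was that of the duodenal genes Cybrd1 and Slc40a1 described below, so gut position is not separated from a tumour change. The call for Wfdc18 ended without any 1 of the WT libraries (adjusted p = 0.0512 to 0.0593) and that for Akp3 in 5 of the 6 refits without 1 library (adjusted p = 0.05 to 0.121). Dpcr1, Atg9b and Fam151a overlap other annotated genes, and the strand setting is not known.

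Lists of gastric-type and of regenerative epithelium were called upward at the preset correlation and not at the estimated one. Of 12 tested genes of the list of serrated and gastric-type epithelium, 8 rose and 1 fell (9 and 2 adjusted over the list alone). The list was called upward (camera adjusted p = 1.75e-08, and adjusted p = 0.294 with an estimated correlation). Members nearly absent from WT intestine passed the filter only through counts in all 3 tumours, so they could come out only as rises. Over all 20 list genes in the table, the median log2 ratio to WT was 4.27, 0.87 and 0.859 in DKO tumours 1 to 3. Vsig1, a junctional protein of gastric epithelium (X chromosome, 140907608 to 140939472), was 1360 times higher (95% interval 244 to 53800), and Tff1, a gastric trefoil peptide (chromosome 17, 31161395 to 31165277), 949 times higher (170 to 37500, and 655 times without DKO tumour 3), each with a WT total of 1 count, in WT intestine 2 and 3 respectively, so no ratio exists without that library. Ctse, the gastric protease cathepsin E, rose from 2.47 CPM in WT intestine (SD 0.83, n = 3) to 250, 16.9 and 84.4 CPM in DKO tumours 1 to 3, a log2 fold change of 5.54 that was 4.33 without DKO tumour 1 (adjusted p = 0.00429). Gkn1, a secreted protein of gastric surface cells, was at least 190-fold higher, with 35.1, 1.61 and 3.78 CPM in DKO tumours 1 to 3, and its bound was 34.1 without DKO tumour 1. The Gkn1 call ended without any 1 of the WT libraries (adjusted p = 0.0595 to 0.0678). The member that fell was Duox2, an oxidase subunit (log2 fold change -1.78, adjusted p = 0.0329, and -2.49 without DKO tumour 1). DKO tumour 1 also held 294 CPM of Tff2 and 103 CPM of Muc6, products of mucous glands of the stomach and duodenum, against at most 1.68 CPM of either in the other libraries. With that tumour left out and the gene set kept, 8 list members rose and 2 fell. When the filter was applied anew to 5 libraries, only 5 members could be tested without any 1 of the tumours, and the list call ended each time (adjusted p = 0.267, 0.336 and 0.824 without DKO tumours 1 to 3). Of these 5 members, 1, 2 and 2 rose and 2, 0 and 1 fell. With the gene set kept the list was called upward without any 1 of the tumours (adjusted p at most 5.87e-06). Members nearly absent from WT intestine entered that set only through counts in all 3 tumours, the omitted one included. The filter on 5 libraries shuts such members out, so neither fit settles whether the call depends on 1 tumour. Of the regenerative and fetal-like list, 13 of 13 tested genes rose (13 adjusted over the list alone, camera adjusted p = 1.82e-32, and adjusted p = 0.0565 with an estimated correlation). Il1rn, the interleukin 1 receptor antagonist, went from 1.9 to 143 CPM (log2 fold change 6.22, SE 0.22). Anxa1, an annexin induced in repair, rose by 4.78 (SE 0.248), Anxa3 by 3.56 (SE 0.132) and Krt7, a keratin, by 3.03 (SE 0.207).

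**Figure D1:**
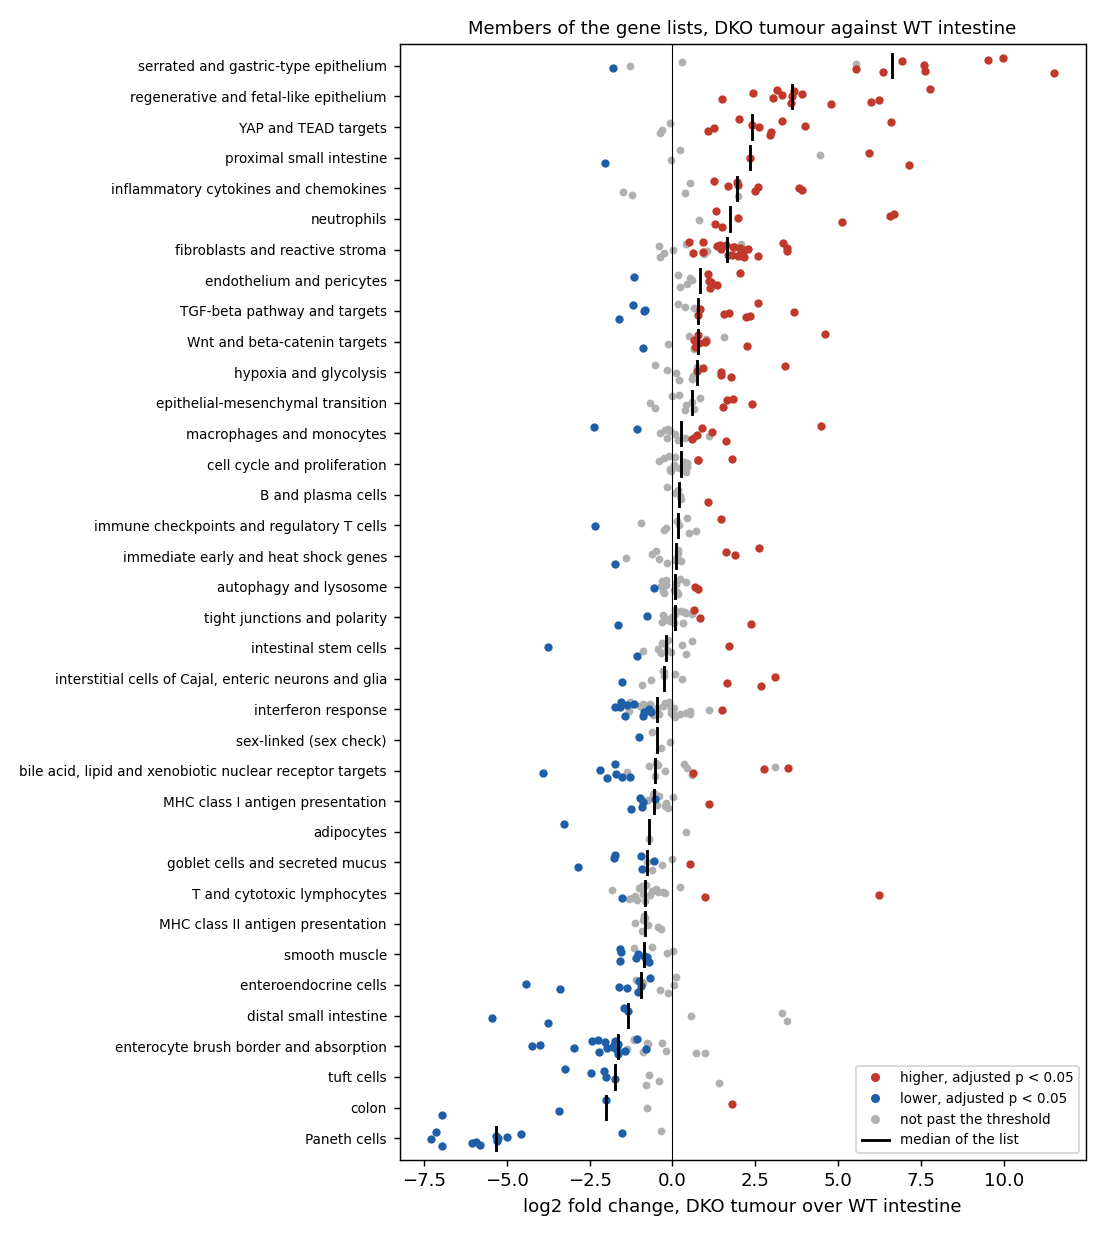
Log2 fold change of DKO tumour over WT intestine (x axis) for each tested member (points) of the gene lists with 3 or more tested genes (y axis), coloured by the edgeR call, with the median of each list as a bar; genes without reads in a group stand at their bound. Serrated and gastric-type genes lie farthest right (median 6.62) and Paneth cell genes farthest left (median -5.31). Gastric-type members nearly absent from WT intestine were tested only through counts in the tumours, which raises that median.

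Lists of Paneth, enterocyte, goblet, enteroendocrine and tuft cell genes were called downward at the preset correlation and not at the estimated one. Paneth cell genes fell in 12 of 13 cases (12 adjusted over the list alone, camera adjusted p = 1.67e-22, and adjusted p = 0.0565 with an estimated correlation). Lyz1, the Paneth cell lysozyme, went from 8892 CPM (SD 2300, n = 3) to 373 CPM (SD 185, n = 3), a log2 fold change of -4.57 (SE 0.472). Ang4, an antimicrobial angiogenin, fell by 6.95 (SE 0.615) and the alpha-defensin Defa17 by 5.80 (SE 0.481), or 6.38 without DKO tumour 1. Of the 10 largest falls, 7 were alpha-defensins or the related AY761184, whose near-identical sequences make the value of a single member uncertain. Enterocyte genes fell in 18 of 28 cases and rose in 0 (24 fell adjusted over the list alone, camera adjusted p = 6.41e-11, and adjusted p = 0.294 with an estimated correlation). Lct, the lactase of the brush border, went from 2010 to 107 CPM (log2 fold change -4.23, SE 0.328) and Dpp4, a brush border peptidase, from 1920 to 247 CPM (-2.96, SE 0.24). Goblet cell genes fell in 6 and rose in 1 of 11 cases, the same counts adjusted over the list alone (camera adjusted p = 0.00266, and adjusted p = 0.499 with an estimated correlation). Zg16, a mucus layer lectin, went from 2860 to 861 CPM, whereas Muc2, the main intestinal mucin, was at 1450 CPM (SD 92.9) and 855 CPM (SD 513), with an adjusted p of 0.164 that became 0.00457 without DKO tumour 2. Enteroendocrine genes fell in 8 of 15 cases (8 adjusted over the list alone, camera adjusted p = 0.000962, and adjusted p = 0.162 with an estimated correlation), led by the hormone genes Nts (-4.40, SE 0.71) and Gcg (-3.39, SE 0.575), which were at -6.10 and -4.55 without DKO tumour 2. Tuft cell genes fell in 5 of 9 cases (5 adjusted over the list alone, camera adjusted p = 0.00324, and adjusted p = 0.499 with an estimated correlation), among them the channel gene Trpm5, from 17.1 to 1.80 CPM. Without DKO tumour 3, the falls numbered 10 of 28 for enterocytes, 3 of 11 for goblet cells and 3 of 15 for enteroendocrine cells. Without WT intestine 2 or 3 the last count was 5. The tumours differed in the markers of gut position described below, and ileal bile acid genes were high only in DKO tumour 2. Gut position is therefore not separated from a tumour change in these falls, those of Nts and Gcg included.

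The stem cell list was not called, while YAP and Wnt target lists were called upward at the preset correlation and not at the estimated one. Of 14 stem cell genes, 1 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.451), and the sign of their median turned under library totals. Olfm4, a marker of crypt base cells, went from 476 CPM (SD 206, n = 3) to 35.2 CPM (SD 26.4, n = 3), a log2 fold change of -3.75 (SE 0.588), and of -4.58 without DKO tumour 1. Lgr5, a Wnt receptor partner of stem cells, was at 18.5 CPM (SD 5.08) and 9.92 CPM (SD 13.4, adjusted p = 0.461), and without DKO tumour 1 its log2 fold change was -3.08 (adjusted p = 0.00133). Targets of YAP and TEAD rose in 10 of 13 cases (10 adjusted over the list alone, camera adjusted p = 4.49e-08, and adjusted p = 0.294 with an estimated correlation), including Ereg, an EGF receptor ligand, from 15.3 to 94.5 CPM, and F3, tissue factor, from 10.3 to 164 CPM. Wnt targets rose in 8 and fell in 1 of 14 cases (8 and 1 adjusted over the list alone, camera adjusted p = 0.00867, and adjusted p = 0.499 with an estimated correlation). Cd44, a hyaluronan receptor, went from 37.1 to 176 CPM, and the gene that fell was Axin2, a feedback target of the pathway (-0.88, adjusted p = 0.0354). The Wnt list call ended without DKO tumour 1 (adjusted p = 0.168), and its rises numbered 5 without that tumour, 3 without DKO tumour 3 and 2 without WT intestine 2. Cell cycle genes rose in 3 of 20 cases (2 adjusted over the list alone, camera adjusted p = 0.125, and adjusted p = 0.744 with an estimated correlation), with Rrm2, a ribonucleotide reductase subunit, at 18.6 and 64.6 CPM. That list was called upward without WT intestine 3 (0.0304) or DKO tumour 3 (0.0453), the latter not with the gene set kept (0.071). Mki67, a marker of cycling cells, was at 195 CPM (SD 79.3) and 146 CPM (SD 20, adjusted p = 0.33), and without WT intestine 1 its log2 fold change was -0.73 (adjusted p = 0.0158).

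At the preset correlation only, the lists of fibroblasts and of endothelium were called upward and that of smooth muscle downward. Of 30 genes of fibroblasts and reactive stroma, 22 rose and 0 fell (23 rose adjusted over the list alone, camera adjusted p = 8.25e-14, and adjusted p = 0.228 with an estimated correlation). Col1a1, a chain of collagen I, went from 20.3 CPM (SD 5.95, n = 3) to 121 CPM (SD 31.1, n = 3), and Sparc, a matrix glycoprotein, from 57.1 to 173 CPM. Endothelial and pericyte genes rose in 6 and fell in 1 of 12 cases (8 and 1 adjusted over the list alone, camera adjusted p = 0.00867, and adjusted p = 0.499 with an estimated correlation), including Vwf, von Willebrand factor (2.03, SE 0.324). Smooth muscle genes fell in 9 of 13 cases (11 adjusted over the list alone, camera adjusted p = 0.000265, and adjusted p = 0.435 with an estimated correlation), with Mylk, a myosin kinase, at 638 and 308 CPM. Acta2, an actin of muscle and activated fibroblasts, was at 180 and 139 CPM (adjusted p = 0.134). The falls in smooth muscle numbered 5 without DKO tumour 2 and 4 without DKO tumour 3. In the TGF-beta list 8 genes rose and 4 fell of 15 (8 and 4 adjusted over the list alone, camera adjusted p = 0.00536, and adjusted p = 0.233 with an estimated correlation). Tgfbr2, a receptor, rose by 2.57 (SE 0.229) and Pmepa1 by 1.695 (SE 0.171), whereas Smad7, Bambi, Skil and Tgfbi fell. Tgfb1 itself was at 7.87 and 14 CPM (adjusted p = 0.0229), a call that ended without WT intestine 2 (0.0887), DKO tumour 2 (0.0644) or DKO tumour 3 (0.0713). Genes of epithelial-mesenchymal transition rose in 4 of 13 cases (4 adjusted over the list alone, camera adjusted p = 0.0115, and adjusted p = 0.294 with an estimated correlation), and the largest of the rises named by the rule was in the epithelial keratin Krt18 (2.40, SE 0.214). That list mixes epithelial genes such as Cdh1, Epcam and Krt18 with mesenchymal regulators such as Snai1 and Zeb1. Its upward call therefore gives no direction of the transition. Interstitial cell, neuron and glia genes rose in 3 and fell in 1 of 11 cases (the same adjusted over the list alone, camera adjusted p = 0.67), a list whose median also turned in sign under library totals, with the pacemaker markers Ano1 at 9.56 and 61.1 CPM and Kit at 20.7 and 7.16 CPM. The rises numbered 1 without WT intestine 1 or 2 or DKO tumour 1 or 3.

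At the preset correlation and not at the estimated one, interferon and MHC class I lists were called downward and neutrophil and cytokine lists upward. Interferon response genes fell in 10 and rose in 1 of 39 cases (10 and 1 adjusted over the list alone, camera adjusted p = 0.00867, and adjusted p = 0.744 with an estimated correlation). Ddx58, which encodes the RNA sensor RIG-I, went from 103 CPM (SD 9.54, n = 3) to 38.3 CPM (SD 7.87, n = 3), and Mx1, an antiviral GTPase, from 12.6 to 3.73 CPM, whereas Iigp1, an interferon-induced GTPase, rose from 14.3 to 40.3 CPM. Cxcl10, a T cell chemokine, was at 8.67 and 4.69 CPM (adjusted p = 0.0482), and that call ended without any 1 of the 6 libraries (0.051 to 0.133). MHC class I genes fell in 5 and rose in 1 of 16 cases (7 and 1 adjusted over the list alone, camera adjusted p = 0.0211, and adjusted p = 0.677 with an estimated correlation), with B2m, the invariant light chain, at 1930 and 808 CPM (adjusted p = 0.0328). The B2m call ended under library totals (0.0599) and in 5 of the 6 fits without 1 library (0.0529 to 0.118), all but that without DKO tumour 1. Without DKO tumour 2 both list calls ended (adjusted p = 0.22 and 0.167), and the MHC class I call ended without WT intestine 1 as well (0.0889). The falls among interferon genes numbered 5 without WT intestine 2 or 3, 4 without DKO tumour 3 and 16 without DKO tumour 1, and those among MHC class I genes 3, 1 and 3 without WT intestine 1, 2 and 3, 2 without DKO tumour 2 and 0 without DKO tumour 3. No MHC class II gene of 8 passed the edgeR test, with 1 lower at an unadjusted p under 0.05 and 1 lower by DESeq2 (camera adjusted p = 0.139, and 0.00437 without WT intestine 3). Of these 8 genes, 0 had a positive log2 fold change, and the median was -0.841.

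T cell and cytotoxic genes rose in 2 and fell in 1 of 21 cases (the same adjusted over the list alone, camera adjusted p = 0.139), with Cd3e, a T cell receptor component, at 10.3 and 3.58 CPM. Only 3 of the 21 genes had a positive log2 fold change, and the median was -0.822. By DESeq2, 2 were higher and 5 lower. The Cd3e call ended without WT intestine 2 (0.0586) or DKO tumour 3 (0.0618), and without DKO tumour 1 the falls numbered 6 of 18. The list was called downward without WT intestine 3 (0.0102), DKO tumour 1 (0.00423) or DKO tumour 3 (0.0343), the last not with the gene set kept (0.128). Eomes, a transcription factor of T and NK cells, had 1 count in WT intestine and 116 in tumours. Cd8a, of cytotoxic T cells, was at 22.3 and 10.1 CPM (edgeR adjusted p = 0.0843; DESeq2 adjusted p = 0.0244). Gzmb, a cytotoxic protease, was at 29.7 and 21.7 CPM (adjusted p = 0.549), Cd274, which encodes PD-L1, at 6.62 and 9.46 CPM (adjusted p = 0.284), and Ifng had 3 counts in WT intestine and 13 in tumours, too few to test. Of 10 checkpoint and regulatory T cell genes, Tnfrsf18 rose and Ido1, a tryptophan-degrading enzyme, fell (-2.33, adjusted p = 0.000243; 1 and 1 adjusted over the list alone, camera adjusted p = 0.574). Neutrophil genes rose in 7 of 8 cases (8 adjusted over the list alone, camera adjusted p = 1.97e-07, and adjusted p = 0.0565 with an estimated correlation). S100a9 and S100a8, which form calprotectin, were at 6.25 and 5.70 CPM in tumours with 2 WT counts each, and Mmp8, a neutrophil collagenase, was at least 34.8-fold higher. These genes were near the detection limit in WT intestine, and with 1 tumour left out only 4 members could be tested, of which 3 rose without DKO tumour 1 or 2 and 0 without DKO tumour 3. The list call ended without DKO tumour 1 (0.0637) or 3 (0.0514) under that filter, and with the gene set kept it held (4.38e-06 and 2.02e-07), with 3 of 8 members higher without DKO tumour 3. Members nearly absent from WT intestine were in the kept set only through counts in all 3 tumours, so that fit is no independent support. In the fit of all libraries, too, such members could come out only as rises. Without WT intestine 1 or 2 the rises numbered 4. Cytokine and chemokine genes rose in 8 of 13 cases (10 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.000223, and adjusted p = 0.294 with an estimated correlation), and in 5 without WT intestine 2 or 3. Il33, an alarmin, went from 54 to 210 CPM and Il11, an interleukin 6 family cytokine, from 0.611 to 8.86 CPM. Macrophage genes rose in 6 and fell in 2 of 18 cases (the same adjusted over the list alone, camera adjusted p = 0.27), with Mrc1, a mannose receptor, at 13.2 and 24.4 CPM. The rises numbered 3 without WT intestine 2 or DKO tumour 2 and 2 without DKO tumour 3. Of 6 B and plasma cell genes, Cd79a rose (1 adjusted over the list alone, camera adjusted p = 0.762).

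**Figure D2:**
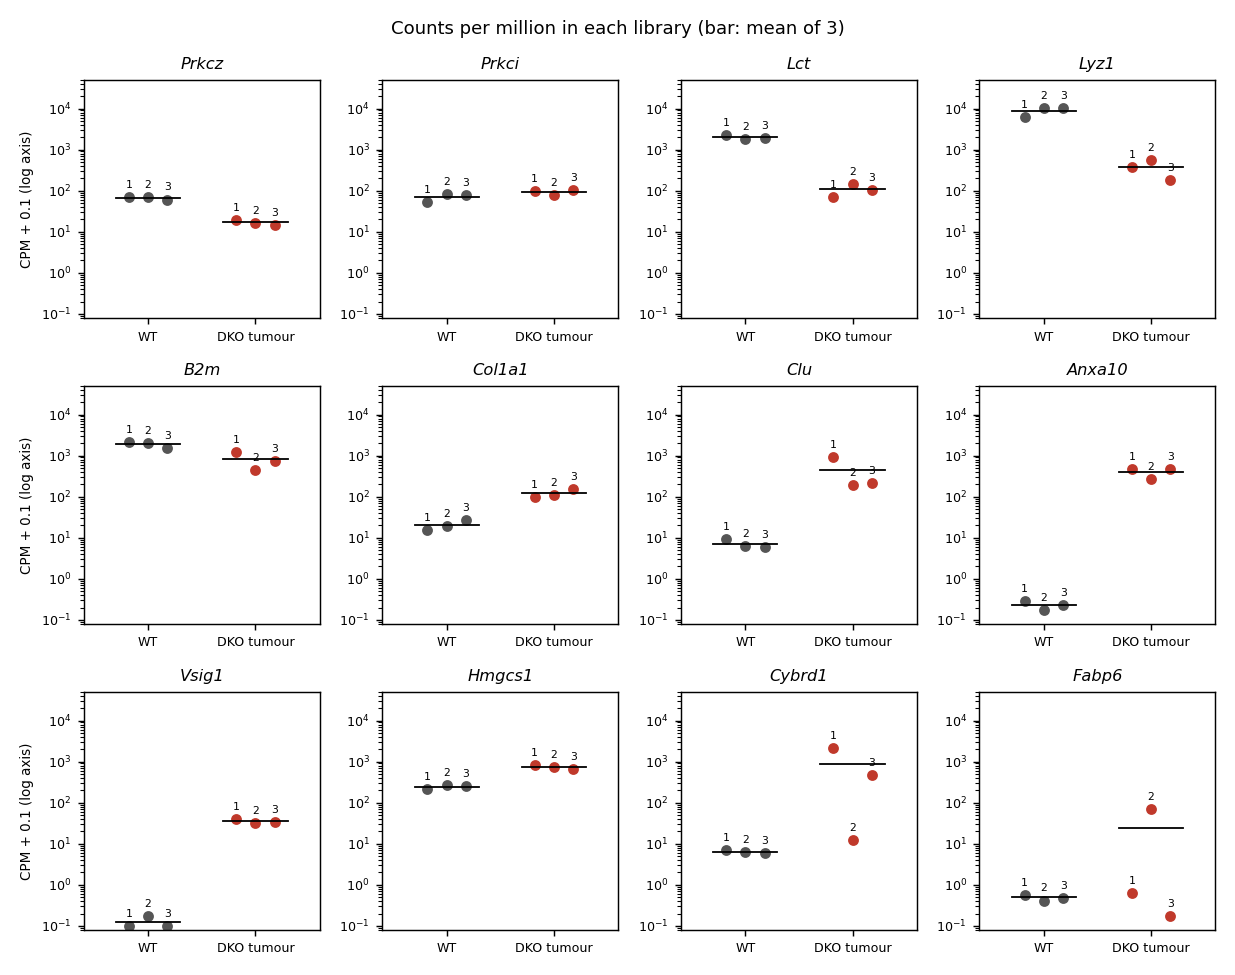
CPM plus 0.1 on a log axis (y axis) of 12 genes in each library (points, numbered by replicate) of WT intestine and DKO tumour (x axis), with the mean of 3 as a bar. Anxa10 lies at 475, 266 and 473 CPM in DKO tumours 1 to 3, whereas Cybrd1 (2190, 11.9 and 460 CPM) and Fabp6 (0.536, 71.8 and 0.0741 CPM) differ between tumours.

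Among other lists, genes of hypoxia and glycolysis rose in 6 of 13 cases (7 adjusted over the list alone, camera adjusted p = 0.00437, and adjusted p = 0.499 with an estimated correlation). Slc2a1, a glucose transporter, went from 13.9 CPM (SD 1.19, n = 3) to 146 CPM (SD 79.6, n = 3), and Car9, a carbonic anhydrase, from 55.4 to 190 CPM. Targets of bile acid, lipid and xenobiotic receptors fell in 7 and rose in 3 of 20 cases (9 and 3 adjusted over the list alone, camera adjusted p = 0.0127, and adjusted p = 0.5 with an estimated correlation), a call that ended without WT intestine 1 (0.0655), and the rises numbered 6 without DKO tumour 2. Abca1, a cholesterol exporter, fell by 1.97 (SE 0.195) and Abcg5, a sterol exporter, by 1.53 (SE 0.178), whereas Gsta4, a glutathione transferase, rose by 3.48 (SE 0.401). Tight junction and polarity genes rose in 3 and fell in 2 of 20 cases (the same adjusted over the list alone, camera adjusted p = 0.66), and the rises numbered 6 without DKO tumour 1. Cldn2, a pore-forming claudin, went from 72.9 to 379 CPM and Cldn15 from 652 to 210 CPM. Autophagy and lysosome genes rose in 2 and fell in 1 of 16 cases (0 and 0 adjusted over the list alone, camera adjusted p = 0.949). Of 14 immediate early and heat shock genes, Nr4a1, Ier3 and Hspa1b rose and Atf3 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.696), and 3 fell without DKO tumour 1.

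Markers of gut position and of neighbouring tissues differed between individual tumours. Cybrd1 and Slc40a1, which carry out duodenal iron uptake, were at 2190 and 1739 CPM in DKO tumour 1 and 460 and 432 CPM in DKO tumour 3, against 11.9 and 55.3 CPM in DKO tumour 2 and at most 6.80 and 14.7 CPM in WT libraries. The ileal bile acid genes Fabp6 and Slc10a2 were at 71.8 and 46.8 CPM in DKO tumour 2 and at most 0.536 and 2.67 CPM in every other library. Proximal genes rose in 3 and fell in 1 of 7 cases (the same adjusted over the list alone, camera adjusted p = 0.451), and 1 rose without WT intestine 2. Distal genes fell in 4 of 7 cases (2 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.152), and 2 fell without WT intestine 1 or DKO tumour 3. Without DKO tumour 2 both lists were called, at 0.00239 and 0.00431. Colon genes rose in 1 and fell in 3 of 5 cases (1 and 4 adjusted over the list alone, camera adjusted p = 0.0673), and the list was called downward without WT intestine 2 or 3 or DKO tumour 2 or 3 (0.000976 to 0.0304). The 14 pancreatic acinar genes held 0.102% of counts in DKO tumour 1 and at most 0.00383% elsewhere, with Ctrb1, a chymotrypsinogen, at 180 CPM in DKO tumour 1 and at most 0.157 CPM in other libraries. Of the 2 acinar genes that could be tested, Cela1 rose. Of 3 adipocyte genes 1 fell (1 adjusted over the list alone, camera adjusted p = 0.59), and Car3, an abundant adipocyte gene, was at 27.3 CPM in WT intestine 3, 5.66 CPM in WT intestine 2 and at most 0.189 CPM elsewhere. Both erythrocyte genes tested rose. Of 4 sex-linked genes tested, 1 fell (2 adjusted over the list alone, camera adjusted p = 0.165).

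In WT intestine alone, the genes with the most reads were those of fat absorption and Paneth cells. Read counts were not corrected for transcript length, so they do not rank transcript abundance. The mean raw counts per library were 156100 (SD 27100, n = 3) for Apoa4, 123200 (SD 29600) for Apoa1 and 112300 (SD 33000) for Apob, which encode apolipoproteins, 117700 (SD 46300) for Lyz1 and 102000 (SD 9730) for Fabp2, a fatty acid binding protein. Over genes with a mean of at least 10 counts, the SD of the difference in log2 (CPM + 1) between a pair of WT libraries was 0.416 on average, and 0.517 between a pair of tumours. It was 0.253 for the pair without WT intestine 1.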

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

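Library totals, upper-quartile factors and the tests that left out a tumour while keeping the genes were chosen only after the data had been seen. The total of 4122 genes was 4681 under DESeq2, 4157 under its size factors, 4014 without a filter, 3697 with a filter of 50 counts and 4217 under upper-quartile factors. Replicate numbers did not pair the samples: across genes, the deviations of libraries with the same number correlated at 0.0138, -0.013 and -0.0334, and no library correlated best with its own number. A block by that number gave 3296 genes (1788 higher and 1508 lower) and called 11 lists up, as before, and 11 down in place of 9, adding the T and cytotoxic list (adjusted p = 0.0324) and the colon list (0.0182). With a log2 change of at least 1 the count was 2215, with 1230 higher and 985 lower, since fewer genes meet both conditions. With 1 library left out, the total ranged from 1866 to 4275, the rises from 1028 to 2216 and the falls from 838 to 2059, with fewer samples in each fit. With the gene set kept, leaving out DKO tumour 3 gave 2060 genes, 1177 higher and 883 lower. Library totals gave 3779 higher and 1065 lower, because they move the median of all genes by 0.258 on the log2 scale. No gene called with all libraries changed sign in these fits.

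With the estimated correlation 0 lists were called up and 0 down in camera, against 11 and 9 at the preset one; 6 of 36 had an unadjusted p under 0.05. With 1 library left out, the lists called up ranged from 8 to 12 and those called down from 7 to 12. The call of the serrated and gastric-type list ended without any 1 of the tumours (adjusted p = 0.267, 0.336 and 0.824 without DKO tumours 1 to 3), with the direction turned downward without DKO tumour 1, because only 5 of its 12 genes passed the filter in 5 libraries. With the gene set kept it was called upward each time (adjusted p = 5.87e-06, 3.15e-17 and 8.05e-11). The kept set holds members nearly absent from WT intestine only through all 3 tumours, and the new filter excludes such members, so neither fit settles the call. With 1 library left out the adjusted p of this list ranged from 9.41e-09 to 0.824. Library totals called 3 further lists and ended 0 calls. With 1 library left out, the log2 fold change of Prkcz ranged from -2.09 to -1.89 and that of Prkci from 0.24 to 0.52; the values with the block were -1.998 and 0.43. Of 148 other named genes tested, 136 were called, and 36 of these lost the call in at least 1 fit without a library, while 0 changed sign. The block by replicate number ended the call of 7 of the 148 and added that of 2, among them Cd8a (edgeR adjusted p = 0.0415). The spread between WT libraries ranged from 0.253 to 0.514 with 1 library left out, and the WT levels moved by less than their SD under scaling. Mean WT levels with 1 library left out ranged from 140600 to 165800 counts for Apoa4. At these depths and 3 mice per group, a change of 2-fold was recovered in 36 of 100 simulated genes. Far fewer genes changed in that simulation than were called here, so its threshold was stricter and the share is not that of these data. A gene without a call is still not shown to be level.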

Other observations

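The lists and tests in this part were chosen or written down after the data had been seen. For the lists added here, the camera p was adjusted over these added lists only. That is a smaller family than the lists fixed beforehand, so the correction was milder. Genes of sterol synthesis and uptake, the targets of SREBP2, were higher in DKO tumours in 12 of 13 cases (12 adjusted over the list alone, camera adjusted p = 1.96e-17, and adjusted p = 0.0399 with an estimated correlation). A correction over these and the fixed lists together was not run. The adjusted p values of the 2 families imply that the latter value would exceed the threshold in it. Among those fixed lists the smallest adjusted p with an estimated correlation was 0.0565. Sqle, squalene epoxidase, went from 62.8 CPM (SD 5.71, n = 3) to 277 CPM (SD 48.6, n = 3), and Hmgcs1, an enzyme of the same pathway, from 246 to 748 CPM. Dhcr7, the last enzyme of cholesterol synthesis, was at 42.7 and 55.3 CPM (adjusted p = 0.154). The count was 12 again without DKO tumour 1.

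NRF2 targets rose in 12 and fell in 1 of 25 cases (17 and 2 adjusted over the list alone, camera adjusted p = 1.43e-08, and adjusted p = 0.12 with an estimated correlation), including Nqo1, a quinone reductase (32.3 and 83.3 CPM), and Slc7a11, a cystine transporter (1.32 and 25.7 CPM). The gene that fell was Srxn1, sulfiredoxin. Genes of ERK output and feedback rose in 11 and fell in 1 of 21 cases (13 and 1 adjusted over the list alone, camera adjusted p = 4.92e-06, and adjusted p = 0.223 with an estimated correlation), with the transcription factor Etv4 at 1.11 and 20 CPM, whereas the feedback phosphatase Dusp6 fell (217 and 135 CPM). Antimicrobial genes fell in 6 and rose in 2 of 12 cases (7 and 3 adjusted over the list alone, camera adjusted p = 0.222), with the lectin Reg3g at 2986 and 435 CPM (log2 fold change -2.78, and -3.87 without DKO tumour 1) and the acute phase gene Saa3 at 0.255 and 13.2 CPM. All 3 gasdermin C genes tested fell (3 adjusted over the list alone, camera adjusted p = 0.00821, and adjusted p = 0.223 with an estimated correlation), with Gsdmc4 at 91.8 and 3.93 CPM (log2 fold change -4.55, and -6.06 without DKO tumour 2). Of 2 mast cell genes tested, 1 rose.

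The split into WT intestine and DKO tumour gave 4122 genes, as the only 1 of the 10 splits of the 6 libraries into 3 and 3 to do so, and the highest of the other splits was 0. With 10 splits no share under 0.05 can be reached.

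Of 12 tested genes of the serrated and gastric-type list, 8 rose and 1 fell in DKO tumours. The list was not called with an estimated correlation (camera adjusted p = 0.294). Stomach tissue carried along was tested first as an explanation of the rises. In DKO tumours 2 and 3, 12 markers of stomach and pyloric glands summed to at most 1.94% of the CPM of Anxa10. No stomach or pyloric sample was measured here, and the limits for this share were set after the values were seen. The low share therefore does not decide whether such tissue contributes there. In DKO tumour 1 the same sum was 92.9%, owing to Tff2 and Muc6, so gastric or duodenal gland tissue may contribute in that library. Over the 20 list genes in the table the median log2 ratios to WT were 4.27, 0.87 and 0.859 in DKO tumours 1 to 3 (5.98, 2.31 and 4.64 over the 8 genes called higher, which were chosen for the pattern), and with 1 ileal-type tumour a gradient along the gut stays open. The deletion of both genes and the tumour state are biological explanations that the design does not separate and that were not tested.

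Paneth cell transcripts were lower in DKO tumours. A lower share of epithelium is argued against by 8 pan-epithelial genes, whose median log2 fold change was 0.353, and reads shared between defensin paralogs by the list members outside that family, whose median was -4.94. The highest of the 3 tumours' median log2 ratios to WT was -5, so tumours with duodenal and with ileal markers were both low, but with 1 ileal-type tumour a gradient along the gut stays open. Genotype and tumour state remain open and untested.

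Sterol synthesis genes were higher under each of 4 scalings, with a lowest median log2 fold change of 1.97, which argues against scaling of the libraries. The 3 tumours had medians of 1.92, 1.95 and 1.87 although their positional markers differed, yet a gradient along the gut stays open with 1 ileal-type tumour. A candidate explanation is a low sterol level in tumour cells, under which 8 LXR targets, switched on by oxysterols, would be lower. Their median log2 fold change was -0.174 (0.0879 under library totals), with 2 lower and 1 higher and no call as a list (camera adjusted p = 0.0958), which does not decide it. Genotype and tumour state remain open and untested.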
